A study of Mus musculus with 6 samples.

How the data were processed

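RNA of adult mouse hippocampal neural precursor cells was measured on 6 one-colour Agilent expression arrays (Cy3), one array per sample. The cells came from the dentate gyri of 8-week-old male mice and were grown as an adherent monolayer with EGF and bFGF, each at 20 ng/ml. They were transfected either with a pool of 4 siRNAs against Ldlr or with a non-targeting siRNA pool, the medium was changed after 24 h, and RNA was taken at 48 h. Per the labels, each group held 3 independent experiments from different passages, and 100 ng of total RNA was labelled per sample.

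The deposited scanner tables were made by the authors with Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed signal is an intensity on a linear scale, background-subtracted and detrended spatially and multiplicatively within the array, and not normalized between arrays. The same deposited tables hold the median pixel intensity of each spot and of its local background, with no normalization. The series also has a value table of the same arrays whose deposited values are on a log2 scale. Its 6 columns had medians from 5.70 to 5.75, and each column correlated best across spots with the log2 signal of its own array (Pearson's r from 0.980 to 0.993, against at most 0.986 with another array). The labels name R 3.4.4 and limma 3.34.9 beside Feature Extraction but do not say how the value table was normalized, so it served as an alternative source of values only.

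Each array held 62976 spots, of which 59305 were not controls. Spots marked by the scanner software as non-uniform or population outliers were left out, which removed 140 of 55681 probes, and replicate spots of a probe were averaged. The scanner tables carry no gene names. RefSeq accessions of the probes were therefore matched to the reference tables, which named 28268 probes (21332 gene symbols) and left 27273 unnamed. The tables' headers name the mouse assembly mm9 whereas the reference annotation is of GRCm38.p6, so no genomic positions are given. The log2 processed signal minus the log2 75th percentile of the array was used throughout, and "normalized log2 signal" refers to that value. A probe was tested where it was well above background on all 3 arrays of at least 1 group (28766 probes). The brightest probe stood for a gene, which gave 21523 genes or transcripts, 13819 of them with a symbol and 7704 without. Ldlr has 1 probe.

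Precision is limited by the number of arrays. The signal at the 75th percentile ranged from 205.9 to 966.3 between arrays, and 50.0% to 67.6% of the spots were well above background. No spot was saturated. For a gene that was not well above background on any array of a group, the fold is a lower bound in the processed signal. It is the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own signal.

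The comparison was Ldlr siRNA minus non-targeting siRNA, fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit chosen before the data were examined had no block. A fit with the replicate number as a block was fixed as the alternative at the same time. The labels tie each number to an independent experiment from another passage, and both arrays of a number were on the same slide, so the block stands for the passage and the slide together. Arrays with the same number deviated together from their group means, with correlations across genes of 0.883, 0.381 and 0.786 for replicates 1, 2 and 3, all over 0.1. The highest correlation of each non-targeting array with an Ldlr siRNA array of another number was -0.48, 0.19 and 0.24. Each was below that of its own number, though the limit of 0.1 alone would not tell the pairs apart. The numbers were therefore taken to pair the samples, and the values of the paired fit are given beside those of the unpaired fit. Genes are said to have risen or fallen only where they passed in the paired fit. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1.

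Gene lists (22, with 536 distinct genes) were fixed before the data were examined, and each was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Adjustment was over the 22 lists. Named genes followed a rule fixed at the same time. The rule took up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold and in 1 direction in all 3 pairs. Where fewer passed, the genes with the smallest p filled each direction to 10. It also took from each list the 4 members with the smallest p. Applying the same rule to the paired fit was decided after the data were examined. A further 4 lists of 16 to 48 genes were added after the data were examined.

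Alternatives fixed beforehand were normexp background correction (offset 50), quantile normalization, the median in place of the 75th percentile, the authors' values, no filter or detection on all 6 arrays, the mean of a gene's probes or every probe on its own, an intensity trend, array weights, values within each slide, leaving out each array and each replicate number, an estimated correlation and fry. For normexp the median spot signal was used, since the tables hold no mean signal. Scaling to 5 bright spike-in probes, leaving out patches of low spots on 1 array, and every alternative run within the paired fit were chosen after seeing the data.

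The fits were tested on simulated data with 200 changed genes in each of 5 simulations, built on the measured spread. The paired fit recovered 16.1% of genes changed 1.5-fold, 84.5% of those changed 2-fold and 99.1% of those changed 4-fold, and 9.29% of its calls were false. The unpaired fit recovered 0%, 0% and 7.58%, with 3.85% of its calls false. A list shifted by 0.5 on the log2 scale was called in all 5 simulations in both fits, with 0 other lists called. That shift was larger than every measured list median, the largest in size being -0.30 for cholesterol biosynthesis. Recovery of shifts as small as the measured ones was therefore not tested. The simulated genes varied independently of each other. In the measured data the correlation estimated in the unpaired fit was 0.15 for cholesterol biosynthesis, 0.53 for proliferation, 0.60 for stress response and 0.02 for interferon genes. In the paired fit it was 0.31, 0.0053, 0.018 and -0.0041 in the same order, so cholesterol biosynthesis was then the most correlated of these lists. The simulations therefore cannot show how often camera at the preset correlation calls an unshifted list of correlated genes.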

Results

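The study asked what loss of the low-density lipoprotein (LDL) receptor does to gene expression in adult neural precursor cells, the dividing cells of the hippocampus that give rise to new neurons. Cultures of these cells received siRNAs against Ldlr or non-targeting siRNAs for 48 h, with 3 independent experiments per group (n = 3 against 3 in every comparison). One array was measured per culture. The non-targeting and Ldlr siRNA arrays had 75th percentile signals of 966.3 and 816.3 in replicate 1, 612.5 and 516.2 in replicate 2, and 262.9 and 205.9 in replicate 3. Between 29648 and 40068 spots per array were well above background. The first principal component held 61.7% of the variance and set replicate 1 (scores of -68.1 and -79.4) apart from replicates 2 (31.9 and 10.3) and 3 (55.5 and 49.8), and within each replicate the Ldlr siRNA array scored lower. The second (19.7%) set non-targeting replicate 2 (62.3) apart from the other 5 arrays (-37.3 to 5.86), and the Ldlr siRNA array again scored lower within each replicate. On the third (10.8%) the Ldlr siRNA arrays all scored below the non-targeting arrays, though the nearest ones lay close together, at 27.4, -10.8 and 35.4 with the non-targeting siRNA and -14.4, -24.7 and -12.8 with the Ldlr siRNA in replicates 1, 2 and 3. The array of the non-targeting siRNA was in the same position on all 3 slides, and so was that of the Ldlr siRNA, so the group and the array position coincide.

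The first comparison was of the siRNA target itself. Ldlr, which encodes the receptor that takes up LDL cholesterol, was lower in the culture given siRNAs against it in all 3 pairs. Its normalized log2 signal was 2.87 ± 0.12 (SD, n = 3) with the non-targeting siRNA and 1.498 ± 0.26 (SD, n = 3) with the Ldlr siRNA. The log2 fold change was -1.37 (95% confidence interval -1.89 to -0.85), a 2.59-fold lower signal. The differences within the 3 slides were -1.61, -1.32 and -1.18. In the unpaired limma fit, the adjusted p was 0.271. In the paired fit, with the replicate number as a block, Ldlr fell with an adjusted p of 0.0319 (95% confidence interval -1.67 to -1.07). The paired call ended without a filter on detection (adjusted p = 0.216) and without replicate 1 (0.217), 2 (0.0530) or 3 (0.178).

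**Figure D1:**
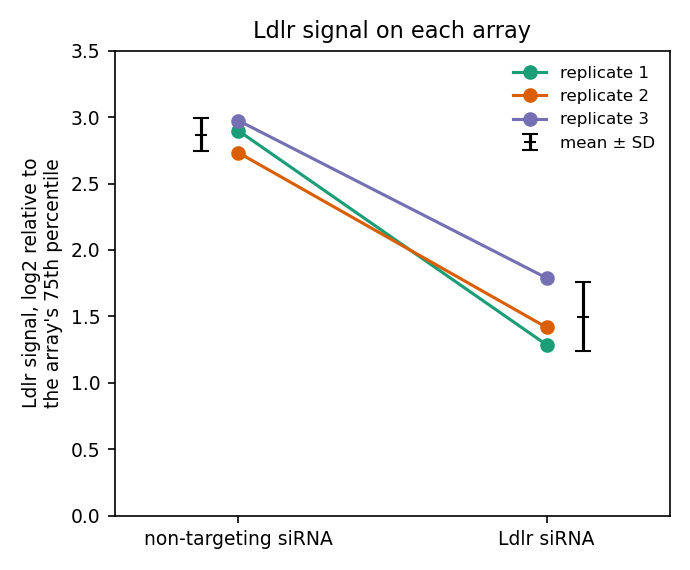
Ldlr signal on each array (log2 relative to the array's 75th percentile) in the non-targeting and Ldlr siRNA groups; points joined by a line are the arrays of 1 replicate and black bars show mean ± SD (n = 3). The Ldlr siRNA arrays lay between 1.29 and 1.79 and the non-targeting arrays between 2.73 and 2.97.

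The second comparison asked which genes differed between the groups. Genes that rose included Casp4, an inflammatory caspase, Lmo2, a LIM-domain transcription cofactor, Pygl, a glycogen phosphorylase, and Cd36, a scavenger receptor for fatty acids and modified lipoproteins. Genes that fell included Atg5, which is needed to form autophagosomes, Lipa, the lysosomal lipase that frees cholesterol from the esters of internalized lipoproteins, Stmn3, a neuronal microtubule regulator, and Vamp7, a SNARE of late endosomes and lysosomes. In the paired limma fit, 447 genes rose and 721 fell, all with an adjusted p between 0.0319, the smallest of any gene, and 0.05. Their median change was 1.63-fold, and 84 and 138 of them changed at least 2-fold. These counts differed from those of the unpaired limma fit, which called 0 genes higher and 0 lower (smallest adjusted p = 0.135), with 527 higher and 584 lower at an unadjusted p under 0.05. The median standard error was 0.28 on the log2 scale in the unpaired fit and 0.09 in the paired fit. In all, 11706 of the 21523 genes tested (54.4%) moved in 1 direction in all 3 pairs, 6674 of them up and 5032 down. Pair differences that were independent and equally likely to be up or down would give 25%. An effect of array position, which was the same in all 3 pairs, would also raise the share, so it does not speak for the siRNA alone. The paired fit called 0 genes without replicate 1, 49 higher and 74 lower without replicate 2, and 0 without replicate 3. It also called 0 genes with no filter on detection.

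The balance of rises and falls depended on the threshold and the scaling. At an unadjusted p under 0.05, the paired fit had 3338 genes higher and 2978 lower, and over all genes tested 12110 were higher and 9413 lower, the reverse of the balance among the adjusted calls. Falls made up 61.7% of the paired calls, against 50.9% with normexp background correction, 73.4% with median scaling and 78.5% with spike-in scaling. With quantile normalization they made up 62.0%, and with the authors' values 59.4%. None of these scalings moved the median of all genes by more than 0.1 on the log2 scale.

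By the rule for named genes, the 12 largest rises in the paired fit had adjusted p between 0.0319 and 0.0471. Casp4 rose 6.56-fold (log2 fold change 2.71 ± 0.29, SE in the paired fit), with 2.48 at its other probe. Lmo2 rose 4.85-fold (2.28 ± 0.12) and Sgip1, an endocytic adaptor, rose 4.604-fold (2.20 ± 0.13). Pygl rose 3.59-fold (1.84 ± 0.11). Esm1, a proteoglycan secreted by endothelial cells, rose at least 4.66-fold, Slc17a9, a vesicular nucleotide transporter, at least 1.93-fold, and Tafa4, a secreted chemokine-like protein, at least 1.84-fold. None of those 3 was well above background on any non-targeting array, and the bounds hold for the processed signal only. With normexp background correction, whose offset of 50 shrinks the changes of dim probes, their log2 fold changes were 1.33, 0.69 and 0.67, below the bounds, and with the authors' values 2.34, 1.08 and 1.09. Myl1 (2.61), Adssl1 (2.53), Spata9 (2.06) and Uba7 (1.77) were well above background on 1 of 3 non-targeting arrays, and Igfbp1 (2.11) on 2 of 3. With normexp these 5 had 1.08, 0.86, 0.70, 0.71 and 1.02, and with the authors' values 1.65, 1.28, 0.99, 1.09 and 1.42, so the size of their rise depended on the processing. Normexp also used the median spot signal, so background treatment alone was not tested. Spata9 had 0.61 with no filter on detection and Tafa4 1.05. The normexp values of Casp4 and Sgip1 were 1.70 and 1.21.

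The 12 largest falls had adjusted p between 0.0319 and 0.0463. Atg5 fell 4.56-fold (log2 fold change -2.19 ± 0.12, SE in the paired fit). Cfl2, an actin-severing cofilin, fell 4.40-fold (-2.14 ± 0.12), with -1.74 at its other probe, and Vamp7 fell 4.20-fold (-2.07 ± 0.14). Lmo1, a relative of Lmo2, fell 3.88-fold (-1.96 ± 0.23). Sybu, which links vesicles to kinesin in axons, fell 3.76-fold (-1.91 ± 0.11), and Tub fell 3.72-fold (-1.90 ± 0.17). Slc16a4 (-1.97), Abcb9 (-1.80), a peptide transporter of lysosomes, and Hs3st2 (-1.77), a heparan sulfate sulfotransferase, also fell, the last being well above background on 2 of 3 Ldlr siRNA arrays. Resp18 fell at least 2.80-fold and Tusc1 at least 2.33-fold, in the processed signal, neither being well above background on any Ldlr siRNA array. With the authors' values they had log2 fold changes of -1.07 and -0.94, below those bounds in size, and with normexp -0.40 and -0.29, neither passing (adjusted p = 0.111 and 0.108 by limma). The normexp values of Slc16a4 and Hs3st2 were -0.82 and -0.54. Gnpda1, an enzyme of hexosamine catabolism, fell by 1.88 on the log2 scale at its brighter probe, whereas its other probe gave -0.15.

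In the unpaired fit the 10 genes with the smallest p in each direction had adjusted p between 0.135 and 0.271, none passing. Those not given above were Cd36 (log2 fold change 1.73 ± 0.11, SE in the paired fit) and Dnah10 (1.69 ± 0.08), a dynein heavy chain of cilia, among the higher genes. Both rose in the paired fit (adjusted p = 0.0319), and Dnah10 was well above background on 1 of 3 non-targeting arrays. Among the lower genes they were Lipa (-1.63 ± 0.08, SE in the paired fit), Stmn3 (-1.68 ± 0.12), Ap3b2 (-1.61 ± 0.10), a neuronal subunit of the AP-3 adaptor, Crtap (-1.51 ± 0.07), Fis1 (-1.24 ± 0.07), a mitochondrial fission factor, and Smpd3 (-1.57 ± 0.12), a neutral sphingomyelinase. All 6 fell in the paired fit with an adjusted p of 0.0319. Smpd3 was well above background on 2 of 3 Ldlr siRNA arrays. With normexp the changes of Dnah10, Ap3b2 and Smpd3 were smaller, at 0.65, -1.04 and -0.61, and Dnah10 had 0.87 with the authors' values.

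**Figure D2:**
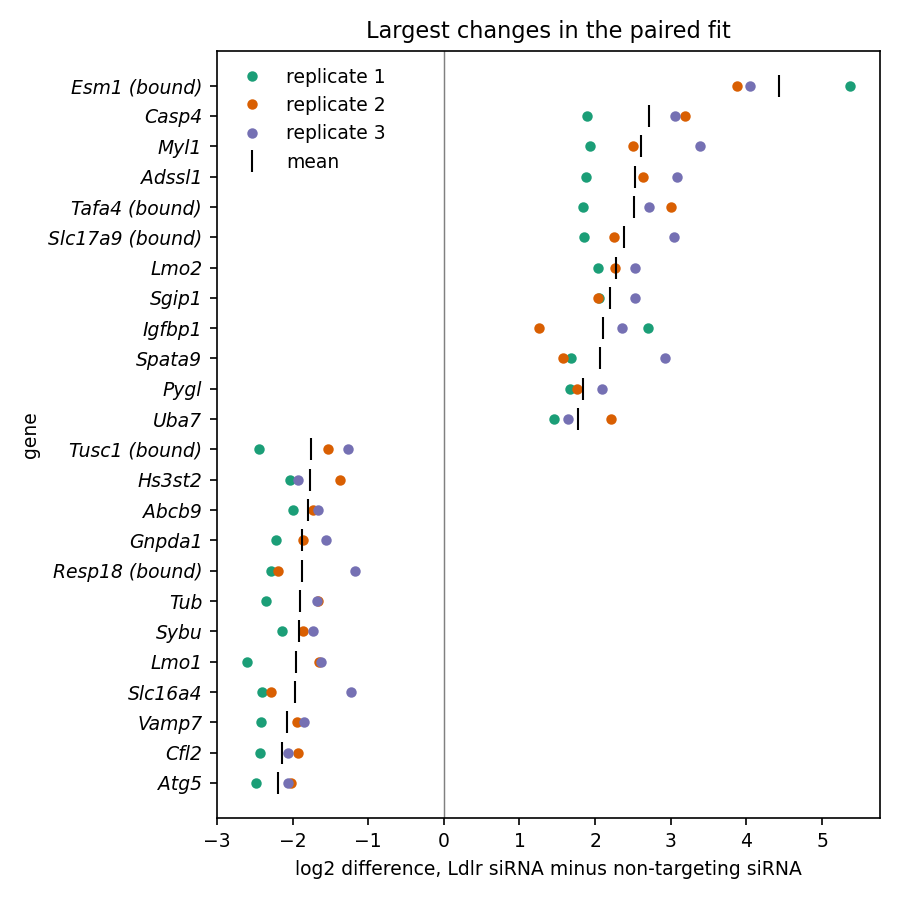
Log2 difference between Ldlr and non-targeting siRNA (x axis) for the 12 largest rises and 12 largest falls of the paired fit (y axis); coloured points are the 3 replicate pairs and black bars the mean. The rule for named genes took only genes whose pairs all lay on 1 side of 0. The means ran from -2.19 (Atg5) to 2.71 (Casp4) for genes not marked "bound". For those marked so, the dimmer group was not well above background, and the plotted difference is not a measure of the fold.

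The third comparison asked whether genes of a process moved together. Cholesterol biosynthesis genes, which cells raise when they sense little cholesterol, were lower after Ldlr siRNA, with negative values for 18 of 22 genes and a median log2 fold change of -0.30. Interferon response genes were higher (18 of 24 positive, median 0.25), whereas genes of proliferation (29 of 39 negative, median -0.11) and of the unfolded protein and integrated stress responses (23 of 28 negative, median -0.19) were lower. Oxidative phosphorylation genes were higher (26 of 30 positive, median 0.13) and immediate early genes lower (12 of 18 negative, median -0.14). These 6 of 22 lists passed camera at the preset correlation in the unpaired fit. With an estimated correlation, 0 lists passed in the unpaired or the paired fit, and fry's directional test, which does not compare a list with other genes, called 0 in both. Fry's mixed test called 7 lists in the unpaired fit and 21 in the paired fit.

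Of the 22 cholesterol biosynthesis genes, 4 fell and 0 rose in the paired fit. Dhcr24, a sterol reductase of the pathway's late steps, fell 2.68-fold (log2 fold change -1.42 ± 0.11, SE in the paired fit). Fdft1, squalene synthase, fell by 0.71, Idi1, isopentenyl diphosphate isomerase, by 0.59 and Fdps, farnesyl diphosphate synthase, by 0.48 on the log2 scale. Adjusted over the list alone, Dhcr24 was lower in the unpaired fit and 11 genes fell in the paired fit. The list's adjusted p was 2.38e-06 in the unpaired and 1.18e-05 in the paired fit with camera at the preset correlation. With an estimated correlation its adjusted p was 0.493 and 0.653. The median of -0.30 was -0.19 without Ldlr siRNA replicate 1, -0.20 without non-targeting replicate 3 and -0.21 with array weights, and -0.39 with spike-in scaling, so its size moved with single arrays and scaling.

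The lists of sterol regulators and of sterol efflux gave no such grouping, which does not show that sterol regulation was unchanged. Of 15 tested regulators and further targets of SREBP, the transcription factors that drive sterol synthesis, 0 passed in either fit, and 0 passed adjusted over the list alone. Stard4, a sterol carrier, had -0.35, and Erlin2 had 0.35. Mbtps1, the site-1 protease, had -0.34 at its brighter probe and 0.51 at the other. Srebf2 had a log2 fold change of 2.50 that rested on 1 low spot of non-targeting replicate 2, with pairs at -0.29, 8.00 and -0.22, and its other probe gave -0.55. The list's median (0.03) and mean (0.13) were positive whereas camera ranked it down (adjusted p = 0.690). Without Srebf2 the median of the other 14 genes was -0.01 and their mean -0.04, so the positive signs rested on that spot. Of 21 genes of efflux, esterification and the oxysterol receptor LXR, Lipa fell and so did Cyp7b1, an oxysterol hydroxylase (-0.68). In the unpaired fit 1 was lower adjusted over the list alone, and in the paired fit 4 fell and 1 rose. That list's median was 0.02, its mean -0.14, and camera ranked it down (adjusted p = 0.338).

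Among 22 tested genes of the LDL receptor family and lipoprotein uptake, Cd36 rose and 5 fell in the paired fit. These were Lrp12 (-0.83), the HDL receptor Scarb1 (-0.68), Lrp1 (-0.64), a large endocytic receptor of apolipoprotein E, Lrp3 (-0.59) and Lrp8 (-0.46), a receptor of reelin and apolipoprotein E. The other probes of Scarb1, Lrp3 and Lrp8 gave -0.39, -0.12 and -0.28. Cd36 was also higher in the unpaired fit adjusted over the list alone, and 3 rose and 6 fell in the paired fit. The list's median was 0.02, its mean -0.04 and camera ranked it down (adjusted p = 0.645). Of 23 fatty acid synthesis genes, the elongase Elovl2 (-0.81), Mid1ip1 (-0.78) and malic enzyme Me1 (-0.45) fell and Agpat2 rose (0.62). The other probes gave -0.35 and -0.16 for Me1 and 0.72 for Agpat2. The list's adjusted p was 0.173 unpaired and 0.0918 paired. It passed, lower, with normexp (adjusted p = 0.0107 unpaired and 0.00925 paired), with no filter on detection (0.0436 and 0.0139), and in the unpaired fit without non-targeting replicate 1 (0.0396) or Ldlr siRNA replicate 3 (0.0189). When adjusted over the list alone, 0 passed in the unpaired fit, and 2 rose and 5 fell in the paired fit. Of 24 fatty acid oxidation and storage genes, Cpt1a, which admits fatty acids to mitochondria, fell (-0.59, with -0.36 at its other probe). The list leaned the other way, with 16 positive and 8 negative values and a median of 0.10, and camera ranked it up (adjusted p = 0.396). Ppard (0.29 to 0.49 over the settings of the unpaired fit), Pnpla2 (0.22 to 0.62) and Plin2 (0.26 to 0.50) were higher without being called in either fit. Adjusted over the list alone, 0 passed in the unpaired fit, and 2 rose and 1 fell in the paired fit.

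Of 39 proliferation genes, 4 fell and 0 rose in the paired fit. They were the cyclin Ccnd2 (-1.04), the helicase subunit Mcm5 (-0.77), the spindle kinesin Kif11 (-0.75) and the replication licensing factor Cdt1 (-0.46). Cdk1 had -0.94 at its brightest probe, -0.81 at another and 0.04 at the last, and did not pass. The paired fit counted 14 falls adjusted over the list alone, and the unpaired fit 0. The list's adjusted p was 0.000740 unpaired and 0.000726 paired, and 0.957 and 0.543 with an estimated correlation. Of 28 stress response genes, Atf5 (-0.96) and Asns (-0.52) of the integrated stress response and Edem1 (-0.88) and Sdf2l1 (-0.62) of the endoplasmic reticulum fell. The corresponding counts adjusted over the list alone were 8 falls and 0. That list's adjusted p was 0.000802 unpaired and 6.66e-05 paired, and 0.957 and 0.543 with an estimated correlation. Both lists lost their unpaired call without Ldlr siRNA replicate 1 (adjusted p 0.359 for proliferation and 0.351 for stress) or without non-targeting replicate 3 (0.282 for each). The size of the shift also moved with single arrays. The proliferation median was -0.00676 without Ldlr siRNA replicate 1 and -0.0118 without non-targeting replicate 3, but -0.34 without non-targeting replicate 1 and -0.28 without Ldlr siRNA replicate 3. The stress median was -0.0377 and -0.0304 in the first pair of settings, and -0.38 and -0.35 in the second. Within the slides of replicates 1, 2 and 3 the medians were -0.17, -0.10 and -0.19 for proliferation and -0.18, -0.24 and -0.14 for stress.

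Interferon genes were measured with siRNA in both groups. Of 24 tested, the antiviral genes Rsad2 (1.498) and Bst2 (0.46) and the immunoproteasome subunit Psmb8 (0.79) rose, and 0 fell. Over the settings of the paired fit Rsad2 ranged from 0.87 to 1.54. Adjusted over the list alone, Rsad2 and Oasl1 (1.29, well above background on 1 of 3 non-targeting arrays) were higher in the unpaired fit and 7 genes rose in the paired fit. The list's adjusted p was 0.000802 unpaired and 0.00874 paired, and 0.493 and 0.543 with an estimated correlation. The median of 0.25 was 0.16 without Ldlr siRNA replicate 3, also 0.16 without both replicate 3 arrays, 0.17 with spike-in scaling and 0.13 with array weights, which ended the unpaired call (adjusted p = 0.0701). Of 30 oxidative phosphorylation genes, 0 passed in either fit, and 0 adjusted over the list alone, with the largest values at Cox7b (0.36) and Ndufa4 (0.30). That list's adjusted p was 0.0299 unpaired and 0.00874 paired, and 0.957 and 0.653 with an estimated correlation. Its unpaired call was lost with normexp (0.0962), quantile (0.0557), median (0.272) and spike-in scaling (0.181) and with no filter on detection (0.163). It was also lost without replicate 2 (0.117) or 3 (0.108), and on leaving out any single array (adjusted p from 0.0640 to 0.200) except non-targeting replicate 2 (0.0334). The list's median of 0.13 was 0.0489 with spike-in and 0.0667 with median scaling. The paired call was lost with normexp (0.196), spike-in scaling (0.108) and without replicate 2 (0.0547) or 3 (0.0586). Of 18 immediate early genes, Ier2 (-0.55) and Egr1 (-0.86) fell. Over the settings of the paired fit Ier2 ranged from -0.64 to -0.14, and 6 settings ended its call. Egr1 ranged from -0.95 to -0.79, and 4 settings ended its call. The paired fit had 3 falls adjusted over the list alone, and the unpaired fit 0. The list passed unpaired (adjusted p = 0.0455) but not paired (0.0589), nor with an estimated correlation (adjusted p = 0.957 and 0.653). The unpaired call was lost under 11 of 21 further settings. These were normexp (0.0962), quantile normalization (0.0557), the authors' values (0.0958), the mean of a gene's probes (0.050009), every probe on its own (0.0504), array weights (0.341), and leaving out replicate 1 (0.215), non-targeting replicate 1 (0.176) or 3 (0.377), or Ldlr siRNA replicate 1 (0.213) or 2 (0.203). The paired fit called the list with normexp (0.0366), spike-in scaling (0.0251), no filter on detection (0.00574), array weights (0.0351) and without replicate 2 (0.0134) or 3 (0.0450). The median of -0.14 was -0.0345 without non-targeting replicate 3 and -0.0417 without Ldlr siRNA replicate 1, but -0.30 without Ldlr siRNA replicate 3, -0.26 without both replicate 3 arrays and -0.25 without non-targeting replicate 2.

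**Figure D3:**
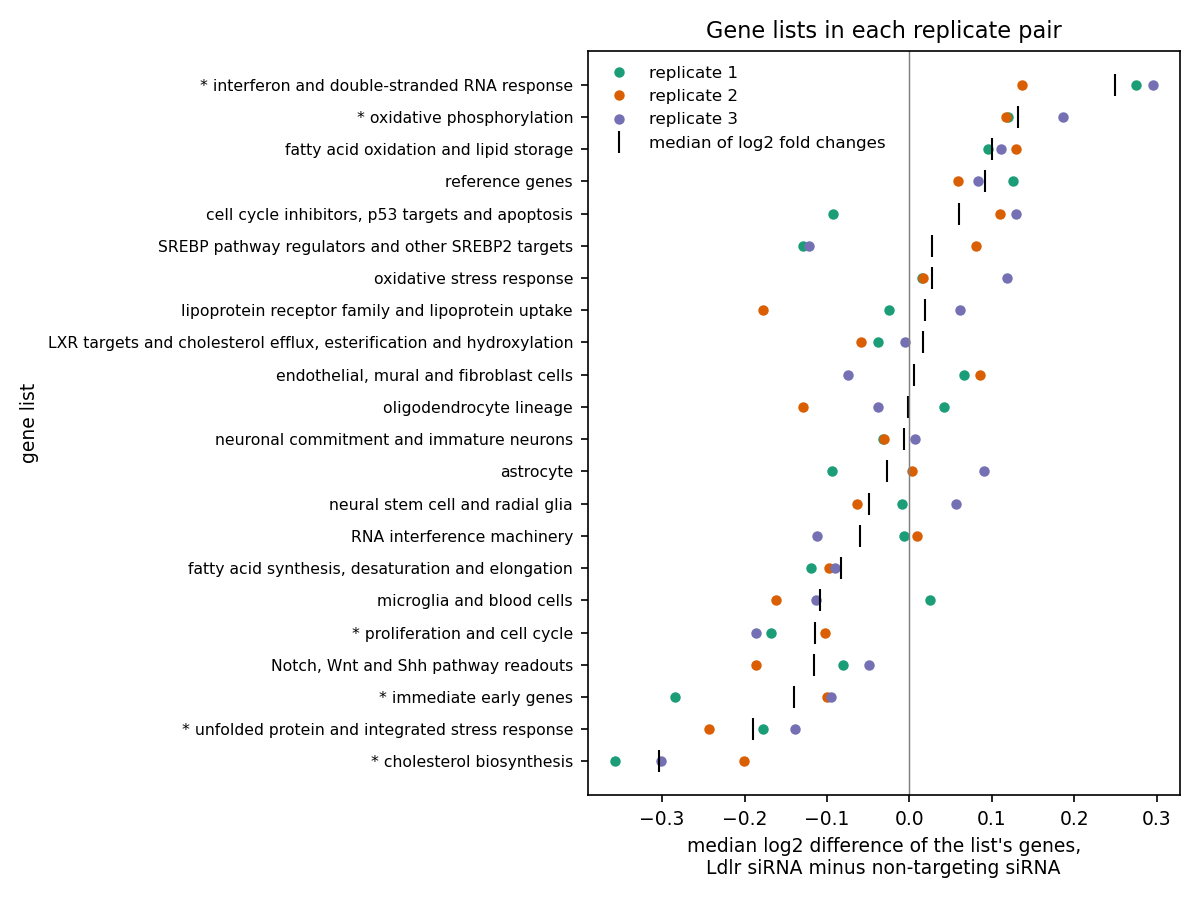
Median log2 difference between Ldlr and non-targeting siRNA (x axis) of the genes of each list (y axis); coloured points are the 3 replicate pairs and black bars the median of the genes' log2 fold changes, and an asterisk marks an adjusted p under 0.05 by camera at the preset correlation in the unpaired fit. Cholesterol biosynthesis lay lowest, with pair medians of -0.36, -0.20 and -0.30.

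Cell identity lists did not pass camera in either fit, though single members did. Of 29 stem cell and radial glia genes, Id2 (0.84) and Id4 (1.12), inhibitors of neurogenic transcription factors, rose. The list's median was -0.05 and its mean 0.03, and camera ranked it up unpaired (adjusted p = 0.957) and down paired. Of 21 neuronal genes, Stmn3, the neuronal tubulin Tubb3 (-1.06) and Igfbpl1 (-1.06, well above background on 2 of 3 Ldlr siRNA arrays) fell and the interneuron factor Dlx2 rose (1.26), with an adjusted p of 0.690 for the list. Over the settings of the paired fit, Igfbpl1 ranged from -1.14 to -0.20, and 6 settings ended its call. Dlx2 ranged from 0.75 to 1.42, so the size of both changes depended on the setting. Aldh1l1 rose (0.49) among 15 astrocyte genes (adjusted p = 0.957 for the list), of which 7 were positive and 8 negative, with a median of -0.03. Without being called in either fit, Atp1b2 was lower (-0.81 to -0.53 over the settings of the unpaired fit). Sparcl1 (0.36 to 0.61) and Slc1a2 (0.35 to 0.54) were higher, also without a call. None of 15 oligodendrocyte lineage genes passed (adjusted p = 0.338 for the list), with Olig1 at -0.53 and Cspg4 at -0.47. Adjusted over the list alone, the counts in the paired fit were 4 risen and 3 fallen stem cell genes, 3 and 3 neuronal genes, 4 and 2 astrocyte genes, and 0 and 0 oligodendrocyte genes. In the unpaired fit 1 neuronal gene was higher and 2 lower adjusted over the list alone, and 0 of the other 3 lists. Of the 18 microglia and blood markers, 6 were bright enough to test, and of the 20 endothelial, mural and fibroblast markers, 8. None of them passed, also adjusted over the list alone (adjusted p = 0.902 and 0.707 for the lists). The largest were Col1a1 at -0.91, well above background on 1 of 3 Ldlr siRNA arrays, and Itgam at 0.32. The endothelial list's median (0.01) and mean (-0.12) differed in sign.

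Of 32 genes of cell cycle inhibition, p53 response and apoptosis, 5 rose and 0 fell in the paired fit. They were the stress-induced Gadd45g (1.00) and Gadd45b (0.99), the pro-apoptotic BH3 genes Bbc3 (0.72) and Bcl2l11 (0.60), and the cyclin kinase inhibitor Cdkn1c (0.44). Trp53, which encodes p53, and Zmat3 were lower without being called in either fit. Over the settings of the unpaired fit, Trp53 ranged from -1.30 to -0.47 and Zmat3 from -0.88 to -0.61. The list had 19 positive and 13 negative values and a median of 0.06. Adjusted over the list alone, 0 passed in the unpaired fit, and 5 rose and 1 fell in the paired fit. The list's adjusted p was 0.396, and 0.0318 unpaired and 0.0400 paired without replicate 1. Of 20 oxidative stress genes, the peroxidase Gpx1 rose (0.42, paired adjusted p = 0.0496), and 0 passed adjusted over the list alone (adjusted p = 0.707 for the list). None of 21 readouts of Notch, Wnt and Shh signalling and none of 11 RNA interference genes passed, also adjusted over the list alone (adjusted p = 0.645 and 0.690 for the lists), with Dll3 at 0.36 and Dicer1 at -0.38. Without non-targeting replicate 1, the signalling list passed, lower (adjusted p = 0.0396). Among 14 reference genes, Ywhaz fell (-0.91, with -0.66 and -1.12 at its other probes), also adjusted over the list alone in both fits, and Gapdh had 0.25 without passing, with 0.16 to 0.26 at its other probes except 1 at 2.33 (adjusted p = 0.817 for the list).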

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

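Scaling to spike-in probes, leaving out the patches of low spots and every alternative within the paired fit were chosen after the results were seen. The replicate block raised the unpaired counts from 0 to 447 genes higher and 721 lower. It passed all 21 of Ldlr and the 20 genes named from the unpaired fit (Ldlr at -1.37, adjusted p = 0.0319). Those 20 genes were chosen on the same arrays for a small p and 1 direction in all 3 pairs, which favours their passing. Of the camera calls at the preset correlation the block ended that of immediate early genes and changed no other. The block also moved fry's mixed test from 7 to 21 lists. Quantile normalization and median scaling each called 1 gene unpaired, Esm1, which is also the 1 named gene then called. Unadjusted p under 0.05 gave 527 higher and 584 lower genes, or 420 and 524 with at least a 1.5-fold change. Array weights called 5034 genes higher and 5617 lower, 21 named genes and 3 lists, with Ldlr at -1.33 (adjusted p = 1.944e-05), but their estimation did not converge and gave Ldlr siRNA replicate 2 a weight of 256.7. Ldlr kept its direction under every alternative run (within slide 1 it was -1.61), with unpaired adjusted p from 1.944e-05 to 1.000 and paired adjusted p from 0.00493 to 0.217. No test could be had within 1 slide for the counts.

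In the paired fit, normexp called 1328 higher and 1375 lower, spike-in scaling 230 higher, detection on all 6 arrays 790 higher and 1099 lower, and an intensity trend 1339 and 1600. These shared 1069, 836, 1094 and 1094 of the 1168 paired calls in the same direction. Without a filter on detection the paired calls were 0 and 0, without replicate 1 they were 0 and 0, without replicate 2 they were 49 and 74, and without replicate 3 they were 0 and 0. Fewer samples leave fewer residual degrees of freedom, and no filter adds tests of dim probes; otherwise the cause was not tested. Signal over background limits the folds of Esm1, Tafa4, Slc17a9, Resp18 and Tusc1 to lower bounds, which hold for the processed signal only. With normexp they had 1.33, 0.67, 0.69, -0.40 and -0.29 on the log2 scale, all smaller than the bounds, and with the authors' values Resp18 (-1.07) and Tusc1 (-0.94) were smaller too. In the unpaired fit, array weights ended the camera calls of proliferation, interferon and immediate early genes. Of the 22 lists, between 2 and 6 passed unpaired when an array or a replicate number was left out. An estimated correlation and fry's directional test gave 0 lists in either fit, and fry's mixed test 21 in the paired fit.

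None of the genes whose direction changed was called in either fit. Mbtps1 had 0.0850 as the mean of its probes and 0.51 at its other probe. Srebf2 had -0.55 with detection on all 6 arrays, at its other probe and with the patches left out, and -0.25 to 3.89 with arrays left out. With arrays left out, Hba-a1 ranged from -0.13 to 0.68, Csf1r from -0.41 to 0.11, Kdr from -0.00719 to 0.64, Pdgfra from -0.55 to 0.29 and Tnrc6b from -0.0631 to 0.31. Pdgfra had 0.0102 with normexp and Col1a1 0.20 with array weights. Apart from the low spot of Srebf2, the cause was not tested.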

Other observations

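The tests of the balance of rises and falls against background treatment, of array position, of clustering of low spots, and of other groupings of the arrays for the gene counts were chosen only after those results were seen. Genes of motile cilia, which beat on ependymal cells, leaned upward. A list of 48 such genes was assembled without Dnah10, after that gene was seen among the rises. Of 23 tested, 18 had positive values, with a median log2 fold change of 0.26 and pair medians of 0.17, 0.10 and 0.24. Rsph9, a radial spoke protein, rose by 0.82 and Ccdc65, of the dynein regulatory complex, by 0.52 in the paired fit, whereas Foxj1, the transcription factor that switches on these genes, fell by 0.63. By camera at the preset correlation the list's p was 0.00872 (adjusted over the 4 added lists, 0.0349), and with an estimated correlation it was 0.0443 (adjusted p = 0.177). In the paired fit the p was 0.0115, and 0.302 with an estimated correlation. A rise of this gene class is a hypothesis from these arrays, and without Foxj1 moving with it the values may reflect single genes.

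None of the remaining added lists passed camera. Lysosome and autophagy genes other than Lipa, Atg5, Vamp7 and Abcb9 had a median of 0.06 over 42 genes (adjusted p = 0.926 by limma's camera), with Ulk1 (-0.49) and the proton pump subunit Atp6v1a (-0.53) falling and cathepsin Ctsl (0.50) rising in the paired fit. Mitochondrial protein import genes had a median of 0.01 over 23 genes, with an unadjusted camera p of 0.867 (adjusted p = 0.926). Targets of bone morphogenetic protein signalling other than Id2 and Id4 had a median of -0.02 over 7 genes, with an unadjusted camera p of 0.484 (adjusted p = 0.926). These p-values do not exclude a shift of those classes.

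Cholesterol biosynthesis genes were lower in the cultures given siRNAs against Ldlr. The arrays do not measure the uptake of LDL cholesterol by these cultures. Scaling between arrays is argued against, since the list's median relative to the median of all genes was -0.25 or lower with normexp, quantile normalization and the authors' values (scalings that move all genes of an array alike cannot change it). A shift of bright probes is argued against too, since 0 of 10000 random lists matched on signal had a median as low as -0.30, the lowest being -0.22. Position on the slide cannot be told apart from the siRNA, because 0 slides held the groups in the other order. The siRNA therefore stays a candidate explanation beside array position, and with an estimated correlation the list's adjusted p was 0.493.

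Falls outnumbered rises among the adjusted calls of the paired fit (721 against 447), but not at an unadjusted p under 0.05 (2978 against 3338). With normexp background correction falls made up 50.9% of the calls, but because rises were gained (1328) as well as falls (1375), so whether the treatment of dim probes made the imbalance stays open. It is argued against among genes above the median signal, where falls made up 71.3% of calls as measured and 68.0% with normexp. Over all calls the shares were 61.7% and 50.9%, so falls were a smaller share among the dimmer genes in both. The balance thus varied with signal, and a signal-dependent difference between arrays was not tested as its cause. Scaling between arrays stays open too. Falls made up at least 59.4% with quantile, median, authors' and spike-in scaling. All 4 lowered the median of all genes, so none of them tested a scaling that raises it. With the authors' values the share was nonetheless below the 61.7% as measured. An effect of the siRNA and array position also stay open.

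On the array of non-targeting replicate 2, 161 spots lay over 3 log2 units below every other array, against 0 on the other 5 arrays. Of these, 99.4% had another such spot within 3 rows and 3 columns, whereas random positions gave at most 24.2%, which is consistent with a local defect of the array surface. Lower transcript levels in that culture are argued against, since other probes of the same 50 genes had a median deviation of 0.0166 (quartiles -0.10 and 0.18), against -5.49 at the low spots. The scanner software had marked 22 of the 161 spots as outliers. Srebf2, at 2.50 with these spots and -0.55 at its other probe, is one of the genes concerned, and leaving the patches out (357 tested genes) gave 1507 paired calls, 1167 of them shared with the 1168.

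The arrays allow 10 splits into groups of 3 and, with labels swapped within pairs, 4, too few for a share under 0.05. In the unpaired fit all 10 splits called as many genes as the real split, which was 0, and the highest of the others was 0. The real split gave 1111 genes at an unadjusted p under 0.05. The 4 splits that grouped both replicate 1 arrays gave 1223 to 6869, whereas the splits that parted replicate 1 and set replicate 2 against replicate 3 gave 121 and 234, which points to replicate 1 standing apart as a structure of the samples. The other splits that parted all 3 pairs gave between 18 and 69. For the lists, 1 of 10 splits passed as many as the real 6, and the highest other passed 5. In the paired fit, 1 of 4 groupings gave as many as the real 1168 genes, the highest other being 0, and 1 of 4 gave as many as the real 5 lists, the highest other being 2.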
